A study of Mus musculus with 50 samples.

How the data were processed

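The deposited table of the authors holds gene counts, whole numbers for 31053 genes by Ensembl gene ID in 50 libraries, with no normalization. Per the labels, cells were sorted from hindlimb muscle by flow cytometry, RNA was isolated in small amounts, and 3' end libraries (QuantSeq) were sequenced as single-end reads of 75 bases. The authors trimmed the reads with cutadapt 2.8 and aligned them with STAR to the mouse genome mm10 (GRCm38). The version of STAR, the counting tool and the gene annotation are not given. Gene symbols and positions were taken from GENCODE vM21, where 30934 of the 31053 IDs had a match, and 36 symbols stood for more than 1 ID. The 50 columns were matched to 16 groups by cell type, strain, day and treatment from the labels. Each library is a pool of 3 or 4 mice, and replicate numbers of different groups carry no stated pairing.

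Counts were analysed in R 4.3.3 with edgeR 4.0.16, one model of group means per cell type. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12277 genes in AEC, 10752 in EC and 11188 in macrophages. Libraries were scaled by TMM. The common biological coefficient of variation was 0.46 in AEC, 0.36 in EC and 0.6 in macrophages. Genes were tested by the robust quasi-likelihood F test of edgeR, and p-values were adjusted by Benjamini and Hochberg over the genes of each of 22 comparisons, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. The comparisons were rHDL against PBS and T2DM against control AEC in each arm, T2DM against control in EC and macrophages at each day, day 7 against day 3, and the interactions of strain with treatment or day.

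Altogether 35 lists of genes for cell types, signalling and metabolism were written down before the data were examined, as were the comparisons, the rule for named genes and the first set of alternatives. Of their 591 genes 589 were in the table. Lists with at least 5 tested genes were tested by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the libraries. A list score is the mean over its genes of log2 CPM with a pseudocount of 1. With an estimated correlation 10 of 191 list calls held. Not all of the 191 are given in the text.

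The rule for named genes was fixed with the design. Among genes with an adjusted p under 0.05, a mean CPM of at least 20, a proper symbol and groups without overlap, the 10 largest changes in each direction were named for effects of treatment or strain and the 5 largest for time and interactions. Up to 4 members with the smallest adjusted p were named from each called list, and where fewer than 3 genes were called also the 3 with the smallest p. A fixed set, among them Ldlr, Abca1, Abcg1, Csf1r, Arg1, Mrc1, Il1b and Icam1, was open to naming in every comparison. Gramd1b at day 7 after PBS and the genes of the averaged comparisons fall outside this rule and were chosen after their values were seen.

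Alternatives were DESeq2 1.42.0, limma voom with library weights, RLE size factors, no filter on low counts, a stricter filter, a fit of the compared groups alone, a block for the replicate number, a non-robust fit and leaving out each library in turn. Where leaving out a library left 2 in a group, the spread was pooled over the groups of the cell type. Chosen after the data were seen were covariates for neutrophil, muscle, lymphocyte and macrophage markers, the removal of the ribosomal RNA locus (Gm42418 and 2 neighbours) and mitochondrial genes, the removal of libraries with over 40% of counts from Gm42418, the adjustment without Ldlr and 3 averaged comparisons. Each comparison was also repeated on other splits of the same libraries, all of them where 10 or 35 exist, 24 drawn for interactions and 40 for averaged comparisons.

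The reversal of the T2DM effect by rHDL was tested by the covariance of both effects across genes, set against 100 simulated data sets without a treatment effect, since both effects share the PBS libraries. The tests were also run on simulated data. Libraries were simulated with the spread of the whole cell type, not of the compared groups, with 100 genes changed 2-fold and 100 changed 4-fold. Of these edgeR recovered 11 and 58 for rHDL in T2DM AEC at day 7 and 14 and 38 for T2DM after PBS at day 7. It recovered 11 and 58 in EC at day 3, and 0 and 0 in macrophages at day 3.

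Total counts per library had a median of 4455061 in AEC, 2446641 in EC and 4105381 in macrophages. The ribosomal RNA locus took 19.61% to 33.56% of counts in AEC, 8.23% to 42.16% in EC and 10.83% to 55.29% in macrophages. A gene without counts in a group was set at a floor of 3 counts over the group, and such floors cover counting error only. Among library pairs of a group none was identical. No library was left out of the results of the first fits. Figures were drawn with matplotlib 3.10.9.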

Results

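Gene counts were measured in 50 libraries of cells sorted from the hindlimb of mice after ligation of the femoral artery. Control C57BL6 mice were compared with a type 2 diabetic (T2DM) strain that lacks the LDL receptor and is altered in IGF-II and ApoB. Effects of diabetes and strain cannot be told apart. Apolipoprotein A-I nanoparticles carrying phosphatidylserine, called rHDL here, were given intravenously, and PBS-treated mice served as untreated samples. Arterial endothelial cells (AEC) of the adductor muscle came from both treatments (25 libraries), while endothelial cells (EC, 13 libraries) and macrophages (12 libraries) of the gastrocnemius came from rHDL-treated mice alone. Cells were taken at day 3 and day 7, with 3 libraries per group and 4 in the rHDL-treated T2DM groups of AEC at day 7 and EC at day 3. A library pooled 3 or 4 mice, and p-values rest on these pooled libraries. Total counts per library ranged from 2308406 to 8975101 in AEC, 1086859 to 9392379 in EC and 3058873 to 9806248 in macrophages. Levels are given in CPM, counts scaled to library size, as mean ± SD over libraries, and log2 fold changes with ± SE from edgeR. Lists of genes were tested with camera, and adjusted p-values are Benjamini-Hochberg values.

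The sorted populations were far apart in their marker genes. The macrophage markers averaged 9.16 ± 0.69 (SD, n = 12) on the log2 CPM scale in macrophages and 3.91 ± 0.68 (n = 13) in EC. The pan-endothelial markers averaged 3.10 ± 0.86 in macrophages and 8.19 ± 0.39 in EC. Each difference had a two-sided permutation p of 1e-05, the smallest that 1e+05 permutations can give. Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919 of mm10), the receptor gene missing in the T2DM strain, lay at 0.503 to 2.02 CPM on average in T2DM groups and between 9.94 and 69.0 CPM in control groups of the 3 cell types.

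In AEC of T2DM mice at day 7, Nfkbiz, Sgk1 and Por were lower after rHDL than after PBS. Nfkbiz (chromosome 16, 55811375 to 55838899), which encodes an atypical inhibitor of NF-kB, fell by 2.48 ± 0.42 on the log2 scale, from 115 ± 93.6 to 20.6 ± 5.13 CPM (adjusted p = 0.00765). Sgk1, a kinase induced by serum and glucocorticoids, fell by 1.97 ± 0.34, from 467 ± 329 to 119 ± 16.7 CPM, and Por, the electron donor of the cytochrome P450 enzymes, fell by 1.84 ± 0.30. Csrnp1, Spsb1, Tuba1c, Arid5a, Enc1, Camta1 and Cyr61 fell by between 1.70 and 3.08. Of 16 hypoxia response genes 4 fell, with 7 adjusted over the list alone: Bhlhe40 by 2.83 ± 0.51, Adm by 2.44 ± 0.52, Hilpda, a lipid droplet protein, by 2.29 ± 0.53 and P4ha2 by 1.49 ± 0.38. Their list median was -0.53 (adjusted p = 0.0035, adjusted p = 0.63 with an estimated correlation).

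Fewer genes rose. Nr1h3, which encodes the oxysterol receptor LXR alpha, rose by 1.68 ± 0.35, from 10.6 ± 2.81 to 34.1 ± 11.3 CPM (adjusted p = 0.0173). Unc5b, a netrin receptor of arterial endothelium, rose by 1.47 ± 0.36, from 40.2 ± 12.1 to 112 ± 21.6 CPM. Phykpl, Prag1, Rnf144a and Sh3rf1 rose by 1.32 to 1.71. Basement membrane genes had a median of -0.52 (adjusted p = 0.0139, adjusted p = 0.63 with an estimated correlation), and Nid1 among their 14 fell by 1.19 ± 0.29, while 4 fell adjusted over the list alone. All 15 glycolysis genes had negative changes, with a median of -0.67 (adjusted p = 0.00152, adjusted p = 0.63 with an estimated correlation). None passed over all genes and 6 fell adjusted over the list alone. The immediate-early genes had a median of -0.77 (adjusted p = 0.0035, adjusted p = 0.63 with an estimated correlation), and Ier3 fell by 2.14 ± 0.51.

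Markers of other cells moved with these genes. The pan-macrophage markers had a median of -1.06 (adjusted p = 0.00152, adjusted p = 0.63 with an estimated correlation), with Lgals3 down by 1.68 ± 0.40. The 5 neutrophil markers had a median of -4.21 (adjusted p = 0.0252, adjusted p = 0.63 with an estimated correlation), with Lcn2 at -4.33 ± 1.27 (adjusted p = 0.115) and S100a8 at -3.76 ± 1.53 (adjusted p = 0.302). The mean neutrophil score was 4.09, 0.175 and 2.75 in the 3 PBS libraries of T2DM mice and between 0.201 and 1.92 in the 4 rHDL libraries. For the interferon response genes the median was 0.34 (adjusted p = 0.0306, and adjusted p = 0.83 with an estimated correlation).

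**Figure D1:**
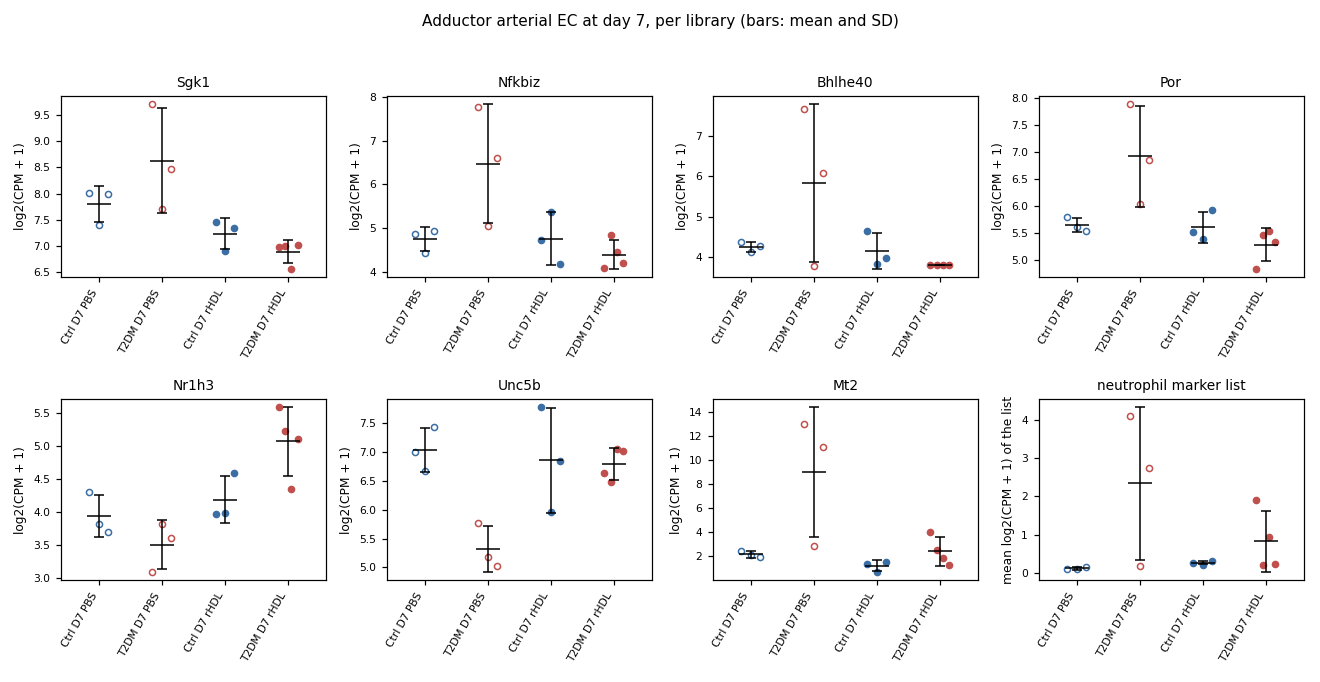
AEC at day 7: each point is a library on a log2(CPM + 1) axis for Sgk1, Nfkbiz, Bhlhe40, Por, Nr1h3, Unc5b, Mt2 and the mean of the neutrophil markers, with control mice in blue, T2DM mice in red, PBS open and rHDL filled, and bars for mean and SD. The 3 PBS libraries of T2DM mice spread widely in Sgk1 (467 ± 329 CPM) and in Mt2 (3580 ± 4430 CPM).

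edgeR called 122 of 12277 genes in this comparison, 12 higher and 110 lower, and 1540 at an unadjusted p under 0.05. DESeq2 called 361, limma voom 401 and edgeR without a low-count filter 408, with a replicate block 8, with the neutrophil score as a covariate 1 and on the compared groups alone 0. Without PBS library 1 no gene was called, without PBS library 2 the count was 727, and without rHDL library 2, 3 or 4 it was 34, 10 and 7. Nfkbiz, Sgk1 and Por were called in 6 of the 7 fits that left out 1 library, Nr1h3 in 5 and Unc5b in 1. The hypoxia, glycolysis, pan-macrophage and immediate-early lists had medians of -0.27, -0.33, -0.72 and -0.16 without PBS library 1 and lost their calls, and the hypoxia median was -1.02 without PBS library 2 and -1.27 without rHDL library 1. The basement membrane list lost its call without PBS library 1 (-0.16) or rHDL library 3 (-0.51) and was at -0.79 without PBS library 2, and the neutrophil list without PBS library 1 or 3 (-2.24 and -4.24) or rHDL library 2, 3 or 4 (-3.83, -3.84 and -3.86). The interferon list turned to -0.16 without PBS library 1 and also lost its call without rHDL library 2, 3 or 4 (0.28, 0.22 and 0.29), while its median was 0.98 and 0.52 without PBS library 2 and 3 and 0.59 without rHDL library 1.

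In the other 3 arms of AEC edgeR called no gene for rHDL. In control mice at day 3, 350 genes had an unadjusted p under 0.05, with the smallest for Nfx1 at -0.90 ± 0.26, Mat2a at -0.93 ± 0.27 and Kat7 at -1.06 ± 0.31 (adjusted p = 1 for each). Here the pan-macrophage markers stood higher as a list, with a median of 2.31 (adjusted p = 7.16e-08, adjusted p = 0.546 with an estimated correlation), Csf1r at 2.83 ± 0.87 and C1qa at 3.35 ± 1.05. MHC class II genes had a median of 3.07 (adjusted p = 2.81e-08, adjusted p = 0.381 with an estimated correlation). The 14 pro-inflammatory macrophage genes had a median of 2.05, or 1.87 with genes absent from a group set at their bound (adjusted p = 0.00102, adjusted p = 0.381 with an estimated correlation). Interferon response genes had a median of 1.14 (adjusted p = 4.75e-08, adjusted p = 0.619 with an estimated correlation). Without control rHDL library 3 the pan-macrophage list had a median of 0.37 and the pro-inflammatory list one of 0.78 (1.62 without PBS library 2), and both lost their calls. The pro-inflammatory median was also 3.20 without PBS library 3 and 0.77 without rHDL library 2, and the MHC class II one 4.75 without PBS library 3. Without rHDL library 2 the interferon list had a median of 0.16 and lost its call.

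In control mice at day 7, 527 genes had an unadjusted p under 0.05, led by Copb1, a coat protein of Golgi vesicles, at 1.28 ± 0.33, Dbp, a circadian transcription factor, at 3.48 ± 0.89 and Slk at 0.84 ± 0.23 (adjusted p = 1). The immediate-early genes had a median of -0.63 (adjusted p = 4.42e-04, adjusted p = 0.613 with an estimated correlation). Of them 3 fell adjusted over the list alone, with Dusp1 at -1.61 ± 0.48, Fos at -1.59 ± 0.60 and Btg2 at -1.04 ± 0.32. Without control PBS library 3 that median was 0.26 and the call was lost, and without PBS library 2 it was -0.98. In T2DM mice at day 3, 339 genes had an unadjusted p under 0.05, led by Id2 at 1.09 ± 0.24, Cldn15, a tight junction protein, at -1.35 ± 0.33 and Atp5d at 0.72 ± 0.23 (adjusted p = 1). The immediate-early genes had a median of -0.37 there (adjusted p = 0.00553, adjusted p = 0.809 with an estimated correlation), with Fos at -1.38 ± 0.61, and of -0.27 without T2DM PBS library 2, where the call was lost, and -0.56 without library 1. In each of these 3 arms DESeq2 called 1 gene and limma voom 0, while edgeR without a low-count filter called 80, 62 and 56 in the order given, and a fit of the compared groups alone 0, 0 and 6.

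At day 3 after PBS, Gramd1b and Abcg1 were higher in T2DM AEC than in control AEC. Gramd1b (ENSMUSG00000040111, chromosome 9, 40293233 to 40531383), which encodes a sterol transfer protein of the endoplasmic reticulum, rose by 2.23 ± 0.34, from 18 ± 10.3 to 82.0 ± 11 CPM (adjusted p = 0.0017). Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988), a cholesterol exporter, rose by 2.8 ± 0.41, from 3.96 ± 1.31 to 28.8 ± 6.36 CPM (adjusted p = 0.0017). Both were called in all 6 fits that left out 1 library. Of the 16 LXR targets and cholesterol efflux genes 1 rose over all genes, and 6 rose and 1 fell adjusted over the list alone, with a median of 0.37 (adjusted p = 8.27e-05, adjusted p = 0.0618 with an estimated correlation), and of 0.56 without control PBS library 2. Apoe was at -1.01 ± 0.22 (adjusted p = 0.183).

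The interferon response genes were higher in T2DM AEC at day 3 as a list. All 23 had positive changes, with a median of 2.39 (adjusted p = 9.84e-30, adjusted p = 0.0654 with an estimated correlation). None passed over all genes, with Ifih1 at 1.25 ± 0.37, Stat2 at 1.59 ± 0.49 and Bst2 at 2.26 ± 0.71 (adjusted p = 0.507 to 0.56), and 22 rose adjusted over the list alone. The MHC class II genes had a median of 4.57, or 4.14 at their bounds (adjusted p = 1.31e-10, adjusted p = 0.0725 with an estimated correlation), with 7 higher adjusted over the list alone and Cd74 at 4.90 ± 1.42. Pro-inflammatory macrophage genes had a median of 2.73, or 1.97 at their bounds (adjusted p = 9.04e-05, adjusted p = 0.0654 with an estimated correlation). That median was 1.74 and 4.24 without control PBS library 2 and 3 and 1.25 and 1.17 without T2DM PBS library 1 and 3, with the call kept. The flow-responsive genes had a median of -0.40 (adjusted p = 0.00114, adjusted p = 0.0654 with an estimated correlation). Thbd, the anticoagulant receptor thrombomodulin, was at -1.33 ± 0.30 and Klf4 at -1.93 ± 0.50, and 2 fell adjusted over the list alone. Aqp1, the endothelial water channel, was at -1.15 ± 0.24 (adjusted p = 0.167). edgeR called 2 of 12277 genes, Gramd1b and Abcg1, both higher. DESeq2 called 40, voom 121, edgeR without a filter 214 and a fit of the compared groups alone 86, and without control PBS library 3 the edgeR count was 5.

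**Figure D2:**
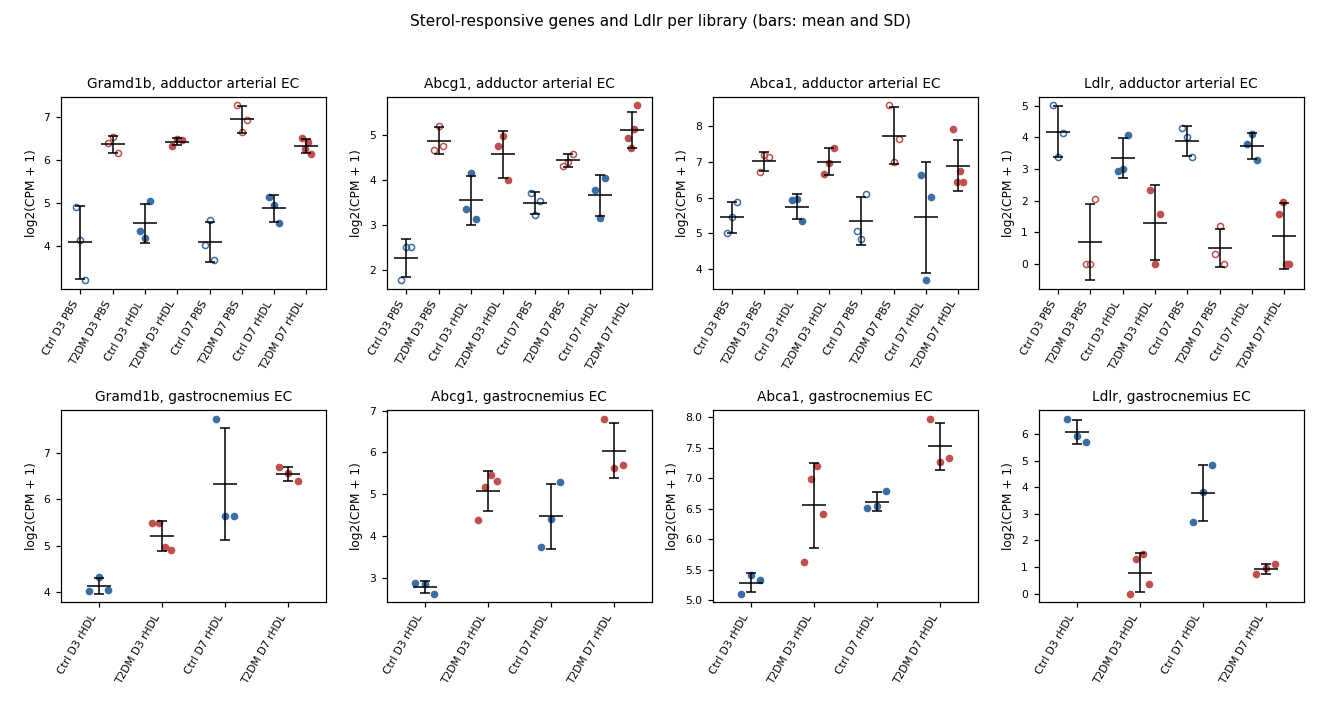
Sterol genes in AEC and EC: each point is a library on a log2(CPM + 1) axis for Gramd1b, Abcg1, Abca1 and Ldlr by day and treatment, with control mice in blue, T2DM mice in red, PBS open and rHDL filled, and bars for mean and SD. After PBS at day 3, Gramd1b was at 82.0 ± 11 CPM in T2DM and 18 ± 10.3 CPM in control AEC.

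At day 7 after PBS, the metallothionein genes Mt1 and Mt2 were higher and Cxcl12, Unc5b and Cxcr4 lower in T2DM AEC. Mt2 rose by 9.97 ± 1.74, from 3.54 ± 0.884 to 3580 ± 4430 CPM (adjusted p = 0.0183), Mt1 by 9.18 ± 1.72 and Serpina3n, an acute-phase protease inhibitor, by 5.87 ± 1.06. Hdc, Cebpd, Csrnp1, Plaur, Irx3 and Rnf19b rose by 2.89 to 3.89, and Angptl4, an inhibitor of lipoprotein lipase, by 3.62 ± 0.76. Gramd1b rose by 2.88 ± 0.34 (adjusted p = 3.29e-05), the smallest adjusted p of the comparison, and was named after its value was seen. Of 16 LXR targets and efflux genes 2 rose, Mylip, which targets the LDL receptor for degradation, by 1.91 ± 0.39 and Abca1, the cholesterol exporter, by 2.46 ± 0.58. Adjusted over the list alone 8 rose and 1 fell, and the median was 0.64 (adjusted p = 0.00515, adjusted p = 0.23 with an estimated correlation).

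Of 19 arterial endothelial markers 3 fell, with 1 higher and 5 lower adjusted over the list alone: Cxcl12 by 1.16 ± 0.22, from 994 ± 158 to 446 ± 165 CPM, Unc5b by 1.73 ± 0.38 and Cxcr4, the receptor of Cxcl12, by 2.10 ± 0.56. The arterial median was -0.38 (adjusted p = 0.00515, adjusted p = 0.317 with an estimated correlation). Kdr, the VEGF receptor, fell by 0.88 ± 0.21 and Tie1 by 0.70 ± 0.18, while the other 16 pan-endothelial markers did not pass. The pan-endothelial median was -0.19 (adjusted p = 0.0378, adjusted p = 0.347 with an estimated correlation), with the call lost without control PBS library 2 (-0.09) or T2DM PBS library 2 or 3 (-0.22 and -0.12). Pdgfd fell by 1.85 ± 0.37, and Pcp4l1, Tppp3, Tmem204, Fam198b, Coro6, Galnt10 and Rnf144a by 1.52 to 2.22. Of 16 hypoxia response genes 3 rose, Pdk1 by 1.88 ± 0.44, Bhlhe40 by 2.35 ± 0.55 and Hilpda by 2.28 ± 0.59, with 7 adjusted over the list alone. Their median was 0.85 (adjusted p = 0.00612, adjusted p = 0.399 with an estimated correlation). Slc16a3, the lactate exporter, rose by 4.00 ± 0.93 among 15 glycolysis genes, with a median of 0.66 (adjusted p = 0.00543, adjusted p = 0.347 with an estimated correlation).

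Markers of leukocytes moved in the same libraries. Lcn2 rose by 7.90 ± 1.83. The neutrophil markers had a median of 9.10, or 7.90 at their bounds (adjusted p = 0.00515, adjusted p = 0.347 with an estimated correlation), with all 5 higher adjusted over the list alone. Itgam rose by 5.40 ± 1.31 and Lgals3 by 1.74 ± 0.44 among 19 pan-macrophage markers. Their median was 1.74 (adjusted p = 6.92e-04, adjusted p = 0.358 with an estimated correlation). Arg1 was at least 68.6-fold higher in T2DM AEC, where it averaged 15.2 ± 14.1 CPM, than in control AEC, where no count was found (floor of 3 counts over the group, adjusted p = 0.0497). The NF-kB targets had a median of 1.14 (adjusted p = 0.0062, adjusted p = 0.23 with an estimated correlation), with Icam1 at 1.01 ± 0.36 (adjusted p = 0.141). The mitochondrially encoded transcripts had a median of -0.63 (adjusted p = 0.00959, adjusted p = 0.358 with an estimated correlation). For the interferon response genes the median was 1.09 (adjusted p = 0.0103, adjusted p = 0.73 with an estimated correlation), and 0 of 23 passed adjusted over the list alone.

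edgeR called 235 genes at day 7 after PBS, 158 higher and 77 lower. Over all 12277 tested genes the libraries of both groups did not overlap in 14.9%, which chance gives in 10%. DESeq2 called 548, voom 661 and edgeR without a filter 669, and a fit of the compared groups alone called 1, a different gene from the 235. The count was 2, 11 and 13 without control PBS library 1, 2 and 3, and 2, 1054 and 90 without T2DM PBS library 1, 2 and 3. Gramd1b was called in all 6 of these fits, Pcp4l1 and Tmem204 in 4, Mt2, Angptl4, Cxcl12 and Mylip in 2 and Abca1, Unc5b, Lcn2 and Arg1 in 1. With the neutrophil score as a covariate, chosen after the data were seen, the count was 1. Without T2DM PBS library 1 the hypoxia and glycolysis lists had medians of 0.00 and 0.44 and lost their calls, as did the arterial list without T2DM PBS library 2 (-0.33; -0.71 without library 1) and the mitochondrial one without control PBS library 3 (-0.38) or T2DM PBS library 2 (-0.39). The interferon list lost its call without control PBS library 1 (0.96) or T2DM PBS library 2 (0.58) or 3 (0.93), the pan-macrophage median was 1.14 without T2DM PBS library 1, and the interferon median was 1.91 with the neutrophil covariate.

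After rHDL at day 3, Gramd1b rose in T2DM AEC by 1.92 ± 0.33, from 22.9 ± 7.90 to 85.4 ± 5.24 CPM (adjusted p = 0.0341), the 1 gene that edgeR called. It kept its call in 1 of 6 fits that left out a library, ending without control rHDL library 1 or 2 or T2DM rHDL library 1, 2 or 3. At day 7 Gramd1b was at 1.47 ± 0.31, Abcg1 at 1.51 ± 0.36 and Ide, the insulin-degrading enzyme, at -1.08 ± 0.26 (adjusted p = 0.499 for each). The LXR targets and efflux genes were higher as a list at day 7, with a median of 0.61 (adjusted p = 1.05e-06, adjusted p = 0.00991 with an estimated correlation). This list had 6 of 16 genes higher adjusted over the list alone and a median of 0.32 without control rHDL library 2. At day 3 their median was 0.28 (adjusted p = 0.00517, adjusted p = 0.164 with an estimated correlation). The interferon response genes had a median of 0.86 at day 3 (adjusted p = 1.88e-06, adjusted p = 0.659 with an estimated correlation). That median was 0.48, 1.79 and 0.51 without control rHDL library 1, 2 and 3 and 0.22 without T2DM rHDL library 1, with the call kept. At day 7 the interferon median was 0.63 (adjusted p = 0.0159, adjusted p = 0.645 with an estimated correlation). The list of day 7 lost its call without control rHDL library 1 (0.19) or T2DM rHDL library 2, 3 or 4 (0.51, 0.37 and 0.47), and had a median of 1.01 without control rHDL library 2. The flow-responsive genes had a median of -0.58 at day 3 (adjusted p = 5.49e-04, adjusted p = 0.164 with an estimated correlation). The prostaglandin transporter Slco2a1 was at -1.56 ± 0.44 and the nitric oxide synthase Nos3 at -0.67 ± 0.29. Beside these, the pan-macrophage markers had a median of -2.19 at day 3 (adjusted p = 1.88e-06, adjusted p = 0.341 with an estimated correlation), -2.15 at their bounds and -0.33 without control rHDL library 3, where the call was lost. edgeR called 0 genes at day 7, with 506 at an unadjusted p under 0.05, DESeq2 6, voom 1, edgeR without a filter 42 and edgeR 1 without T2DM rHDL library 3, and at day 3 edgeR called 1, with 538 at an unadjusted p under 0.05, DESeq2 10, voom 3, no filter 107 and a replicate block or a non-robust fit 0.

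**Figure D3:**
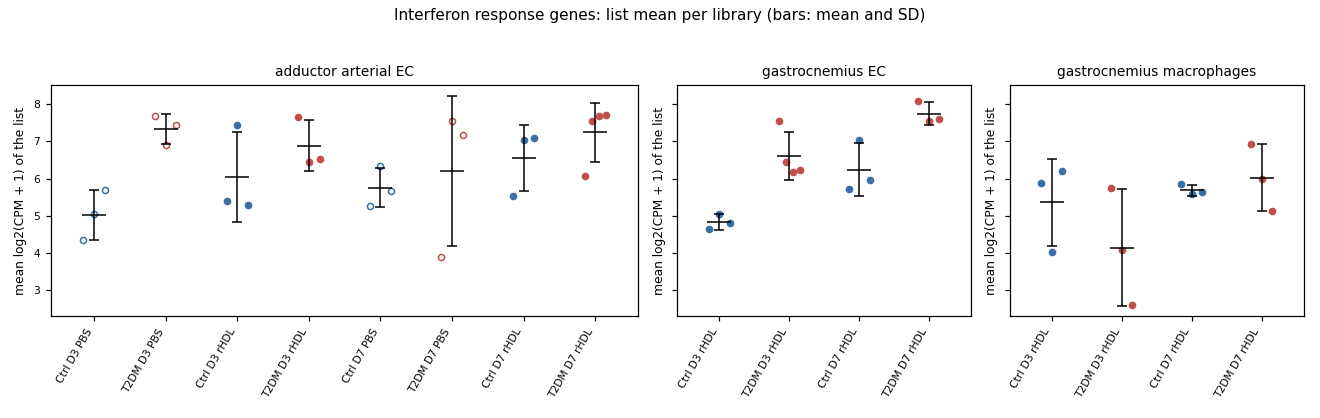
Mean of the interferon response genes per library in AEC, EC and macrophages on a log2(CPM + 1) axis, with control mice in blue, T2DM mice in red, PBS open and rHDL filled, and bars for mean and SD. At day 3 after PBS the 3 T2DM libraries of AEC lay between 6.90 and 7.68 and the 3 control libraries between 4.34 and 5.69.

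Whether rHDL acted differently in T2DM and control AEC was tested as an interaction, and edgeR called no gene at either day. The smallest p-values at day 7 were those of Fzd4, a Wnt receptor, at -1.50 ± 0.31 (adjusted p = 0.247), Nfe2l2 at -1.21 ± 0.29 and Nfkbiz at -2.56 ± 0.61 (adjusted p = 0.345 for both). At day 3 they were those of Enpp4 at -1.16 ± 0.36, Pitpnm2 at 1.29 ± 0.40 and Col6a3 at 2.00 ± 0.63. At an unadjusted p under 0.05 there were 403 genes at day 3 and 1093 at day 7, DESeq2 called 0 and 17, voom 0 and 1 and edgeR without a filter 86 and 187, and without T2DM PBS library 2 edgeR called 184 at day 7. Of the 158 genes higher and 77 lower in T2DM than in control AEC at day 7 after PBS, 66 and 8 changed the opposite way with rHDL and 0 the same way. Both comparisons share the 3 PBS libraries of T2DM mice, which alone makes opposite changes correlate. The covariance of both effects across genes was -0.44 at day 7, against -0.192 in simulated libraries without a treatment effect, a difference of -0.248 with a jackknife SE of 0.356. At day 3 it was -0.19 against -0.204, a difference of 0.014 with an SE of 0.076. Taken from the spread of the T2DM PBS libraries themselves, the covariance without a treatment effect was -0.339 at day 7 and -0.145 at day 3, with differences of -0.1 (SE 0.401) and -0.045 (SE 0.078). No difference exceeded its error.

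Between day 3 and day 7, Fst, Col1a1, Col5a1 and Sdf2l1 fell in AEC of both strains. In control mice after PBS, Fst, the activin antagonist follistatin, fell by 8.53 ± 0.84, from 64.5 ± 49.8 to 0.144 ± 0.249 CPM (adjusted p = 2.35e-07), Lgals1 by 5.49 ± 0.50, from 2320 ± 1710 to 51.4 ± 18.5 CPM, and Basp1 by 5.63 ± 0.74. Of 11 fibroblast markers 3 fell, with 6 adjusted over the list alone: Col1a1 by 5.73 ± 0.71, Postn by 5.65 ± 1.12 and Col5a1 by 4.26 ± 0.97. The list median was -2.17 (adjusted p = 3.34e-07, adjusted p = 0.0114 with an estimated correlation). Of 17 unfolded protein response genes 2 fell, the chaperone Hspa5 by 1.67 ± 0.31 and Sdf2l1 by 3.03 ± 0.66. Their list median was -0.74 (adjusted p = 5.48e-04, adjusted p = 0.0114 with an estimated correlation), and -0.41 without day 3 library 1. Dbn1 fell by 7.94 ± 1.56, and Plxnd1, a semaphorin receptor, rose by 1.17 ± 0.30. The pan-macrophage markers had a median of 1.47 (adjusted p = 6.87e-05, adjusted p = 0.743 with an estimated correlation).

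In T2DM mice after PBS, Fst fell by 8.73 ± 0.91, Apln, the ligand of the apelin receptor, by 5.72 ± 0.53, from 193 ± 21.2 to 3.73 ± 2.02 CPM, and Ctgf by 5.49 ± 0.64. Gabbr2 was at least 175-fold lower at day 7, where no count was found (floor of 3 counts over the group), against 40 ± 3.40 CPM at day 3. Col1a1 fell by 5.20 ± 0.70, Col5a1 by 4.76 ± 1.03 and Col3a1 by 2.38 ± 0.61 among 11 fibroblast markers. Their median was -1.50 (adjusted p = 3.84e-04, adjusted p = 0.24 with an estimated correlation), -0.99 without day 3 library 2 and -2.38 without day 7 library 1. Pdia6 fell by 1.59 ± 0.34 and Sdf2l1 by 3.00 ± 0.66 among 17 unfolded protein response genes. Their median was -0.22 (adjusted p = 0.043, adjusted p = 0.24 with an estimated correlation), and the call was lost without day 3 library 3 (-0.30) or day 7 library 2 (-0.58) or 3 (-0.29), with -0.36 without day 3 library 1. Nfkbiz rose by 2.47 ± 0.46, Nfil3 by 3.60 ± 0.82, Trib1 by 2.28 ± 0.46, Rgs2 by 2.98 ± 0.77 and Nek7 by 1.98 ± 0.38. Csf1r rose by 3.83 ± 0.89 and Lgals3 by 1.97 ± 0.45 among 19 pan-macrophage markers, 12 of which rose adjusted over the list alone. Their median was 3.30 (adjusted p = 2.07e-10, adjusted p = 0.24 with an estimated correlation), and 2.10 without day 7 library 1. The neutrophil markers had a median of 4.70 (adjusted p = 0.0427, adjusted p = 0.681 with an estimated correlation), with the call lost without day 3 library 2 (4.16) or day 7 library 1 or 3 (2.57 and 5.26).

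edgeR called 160 genes over time in control AEC, 2 higher and 158 lower, and 235 in T2DM AEC, 83 higher and 152 lower, with 95 genes in common, all 95 in the same direction. Fst, Col1a1, Lgals1 and Hspa5 in control AEC and Fst, Apln, Gabbr2, Col1a1 and Nfkbiz in T2DM AEC were called in all 6 fits that left out a library. Over all tested genes non-overlapping libraries were seen in 13.1% in control and 16.5% in T2DM AEC, against 10% by chance. In control AEC the count was 100 without day 3 library 1 and 98, 96 and 100 without day 7 library 1, 2 and 3, and in T2DM AEC it was 107, 105 and 114 without day 3 library 1, 2 and 3 and 138, 719 and 145 without day 7 library 1, 2 and 3. A fit of the compared groups alone gave 79 and 36 genes, 73 and 33 of them shared with those counts, and the covariate of the neutrophil score left 93 in T2DM AEC.

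In EC of the gastrocnemius after rHDL, T2DM mice had higher interferon response genes and lower cholesterol biosynthesis genes at day 3. Gbp9, an interferon-induced GTPase, rose by 2.02 ± 0.31, from 40.1 ± 10.1 to 163 ± 45.9 CPM (adjusted p = 0.026), and Ldlr fell by 6.16 ± 0.61, from 69.0 ± 22.2 to 0.892 ± 0.897 CPM (adjusted p = 1.25e-04). All 23 interferon response genes had positive changes and all 23 rose adjusted over the list alone, with a median of 1.75 (adjusted p = 6.84e-50, adjusted p = 0.0323 with an estimated correlation). Gbp3 was at 2.84 ± 0.47, Zbp1 at 4.44 ± 0.78 and Ifit2 at 2.50 ± 0.46 (adjusted p = 0.0543 to 0.0742). Of 20 cholesterol biosynthesis genes 3 fell adjusted over the list alone, with a median of -0.58 (adjusted p = 9.13e-09, adjusted p = 0.0027 with an estimated correlation). Dhcr24 was at -2.89 ± 0.68, Srebf2, the master regulator of the pathway, at -1.25 ± 0.29 and Sqle at -2.55 ± 0.73. The LXR targets and efflux genes had a median of 0.65 (adjusted p = 4.88e-08, adjusted p = 0.0393 with an estimated correlation), with 4 higher adjusted over the list alone. Abcg1 was at 2.53 ± 0.44, Mylip at 1.66 ± 0.35 and Abca1 at 1.41 ± 0.33. These 3 lists kept their calls in all 7 fits that left out 1 library, with the LXR median at 0.40 without control library 1. Beside them, the pan-macrophage markers had a median of -1.02 (adjusted p = 7.76e-09, adjusted p = 0.34 with an estimated correlation), with Lyz2 at -1.58 ± 0.42. Fibroblast markers had a median of -0.60 (adjusted p = 6.91e-04, adjusted p = 0.238 with an estimated correlation).

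edgeR called 2 of 10752 genes at day 3, Gbp9 and Ldlr, with 491 at an unadjusted p under 0.05, DESeq2 64, voom 22, no filter 18 and the compared groups alone 5. With Ldlr, which the T2DM strain lacks, left out of the adjustment, edgeR called 0 genes, with Gbp9 at adjusted p = 0.0521. Ldlr kept its call in all 7 fits that left out a library and Gbp9 in 3. The count was 1 without control library 1, 2 or 3 or T2DM library 2, and 6 without T2DM library 1 or 3.

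At day 7 in EC, Irgm2, another interferon-induced GTPase, rose by 3.15 ± 0.50, from 18.1 ± 7.43 to 157 ± 118 CPM, and Ldlr fell by 4.24 ± 0.67 (adjusted p = 0.0446 for both). Dap at -1.36 ± 0.26 and Slc43a3 at 2.08 ± 0.39 followed (adjusted p = 0.0979). Among the interferon response genes, whose median was 1.21 (adjusted p = 3.00e-08, adjusted p = 0.479 with an estimated correlation), 13 were higher adjusted over the list alone. The cholesterol biosynthesis genes had a median of -0.53 (adjusted p = 0.0213, adjusted p = 0.215 with an estimated correlation), with Dhcr24 at -4.17 ± 0.91. LXR targets and efflux genes had a median of 0.65 (adjusted p = 0.00636, adjusted p = 0.479 with an estimated correlation), with Mylip at 1.42 ± 0.36 and Abcg1 at 1.51 ± 0.41. The fibroblast markers had a median of -0.93 (adjusted p = 3.38e-04, adjusted p = 0.215 with an estimated correlation), with Col1a1 at -2.86 ± 0.66 and Col3a1 at -1.80 ± 0.35. The pan-macrophage markers had a median of -1.32 (adjusted p = 5.06e-06, adjusted p = 0.479 with an estimated correlation), with Csf1r at -2.99 ± 0.82, and without control library 1 both were at -0.71. Among these libraries control library 1 had 1086859 counts, 42.16% of them from the ribosomal RNA locus Gm42418.

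edgeR called 2 genes at day 7, with 2071 at an unadjusted p under 0.05, DESeq2 631, voom 3 and edgeR without a filter 300. With Ldlr left out of the adjustment the count was 0, with Irgm2 at adjusted p = 0.0892. The count was 1, 189 and 347 without control library 1, 2 and 3, and 0, 84 and 0 without T2DM library 1, 2 and 3. A stricter filter, a non-robust fit, a replicate block and a fit of the compared groups alone each called 0. The cholesterol list lost its call without control library 2 or 3 or T2DM library 2 (medians -0.51, -0.43 and -0.56), with -0.31 without control library 1, and the LXR median was 0.42 without T2DM library 1.

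Over time in EC edgeR called no gene in either strain. In control mice H19, an imprinted RNA, was at 3.31 ± 0.56, Gbp3 at 2.69 ± 0.49, Gramd1b at 2.56 ± 0.47 and Rsad2, an antiviral enzyme, at 1.90 ± 0.37 between day 3 and day 7 (adjusted p = 0.157 to 0.164). The interferon response genes had a median of 1.81 (adjusted p = 1.62e-26, adjusted p = 0.178 with an estimated correlation), with 20 higher adjusted over the list alone. The cholesterol biosynthesis genes had a median of -0.72 (adjusted p = 0.00145, adjusted p = 0.0925 with an estimated correlation). In T2DM mice Adamts4 was at -2.10 ± 0.34, Sh2d5 at -2.99 ± 0.53 and Irgm2 at 2.33 ± 0.42 (adjusted p = 0.0975). There the interferon response genes had a median of 0.86 (adjusted p = 5.67e-13, adjusted p = 0.303 with an estimated correlation), and of 1.38 without day 3 library 1. At an unadjusted p under 0.05 there were 1051 genes in control and 885 in T2DM mice, DESeq2 called 81 and 26, voom 2 and 30 and edgeR without a filter 22 and 13. edgeR called 2, 2 and 3 genes in control mice without day 7 library 1, 2 and 3. The change of the T2DM effect over time called 0 genes, with 480 at an unadjusted p under 0.05 and 0 by DESeq2 and voom, and Sele, an adhesion molecule, had the smallest p at -4.52 ± 1.30 (adjusted p = 0.864).

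In macrophages after rHDL at day 3, T2DM libraries carried transcripts of skeletal muscle beside the macrophage genes. Of 18 skeletal muscle markers all had positive changes and 17 rose adjusted over the list alone, with a median of 3.49 (adjusted p = 5.18e-22, adjusted p = 0.223 with an estimated correlation). The calcium pump Atp2a1 was at 3.57 ± 1.12, Mb at 4.08 ± 1.31 and Ttn at 4.40 ± 1.44 (adjusted p = 0.681 for each). The smooth muscle markers had a median of 3.22 (adjusted p = 3.31e-10, adjusted p = 0.236 with an estimated correlation) and the pan-endothelial markers one of 1.69 (adjusted p = 1.69e-08, adjusted p = 0.269 with an estimated correlation). The mitochondrially encoded transcripts had a median of 2.14 (adjusted p = 9.32e-10, adjusted p = 0.241 with an estimated correlation). Without control library 2 these 4 medians were 6.43, 5.04, 2.77 and 3.36. Mitochondrial transcripts took 23.24%, 29.28% and 8.93% of counts in the 3 T2DM libraries of day 3 and 2.42%, 13.74% and 3.46% in the control ones, and in T2DM library 3 Gm42418 took 55.29%. The cholesterol biosynthesis genes had a median of -0.97 (adjusted p = 2.03e-06, adjusted p = 0.161 with an estimated correlation), with Cyp51 at -2.33 ± 0.51 and Msmo1 at -1.53 ± 0.43, 2 of 22 lower adjusted over the list alone. The LXR targets and efflux genes had a median of 0.65 (adjusted p = 0.0186, adjusted p = 0.234 with an estimated correlation), with Mylip at 1.60 ± 0.37 and Abca1 at 1.48 ± 0.43, and medians of 0.01 without T2DM library 1 and 0.43 without control library 2, where the call was lost. Ldlr was at -5.83 ± 0.86 (adjusted p = 0.128), the smallest p.

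At day 7 Ldlr again had the smallest p in macrophages, at -5.78 ± 0.86 (adjusted p = 0.14), followed by Slc13a3 at -2.64 ± 0.74 and Smim15 at -0.99 ± 0.29. The smooth muscle markers had a median of 2.19 (adjusted p = 1.23e-05, adjusted p = 0.532 with an estimated correlation), which was -0.49 without T2DM library 3, whose mitochondrial share was 23.83%, and the call was lost. The alternatively activated macrophage genes had a median of -0.27 (adjusted p = 0.00891, adjusted p = 0.301 with an estimated correlation), of -0.46 and -0.16 without control library 2 and 3 and of -0.42 and -0.66 without T2DM library 1 and 2. Arg1 was at -2.25 ± 0.98, the mannose receptor Mrc1 at -0.86 ± 0.45 and Chil3 at -1 ± 0.58 (adjusted p = 1). edgeR called 0 genes at both days, with 801 and 164 at an unadjusted p under 0.05. DESeq2 called 81 and 1, voom 366 and 0 and edgeR without a filter 1 and 1, and without T2DM library 1 edgeR called 1 at day 3. In simulated libraries with the spread of this cell type, edgeR recovered 0 of 100 genes changed 4-fold.

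**Figure D4:**
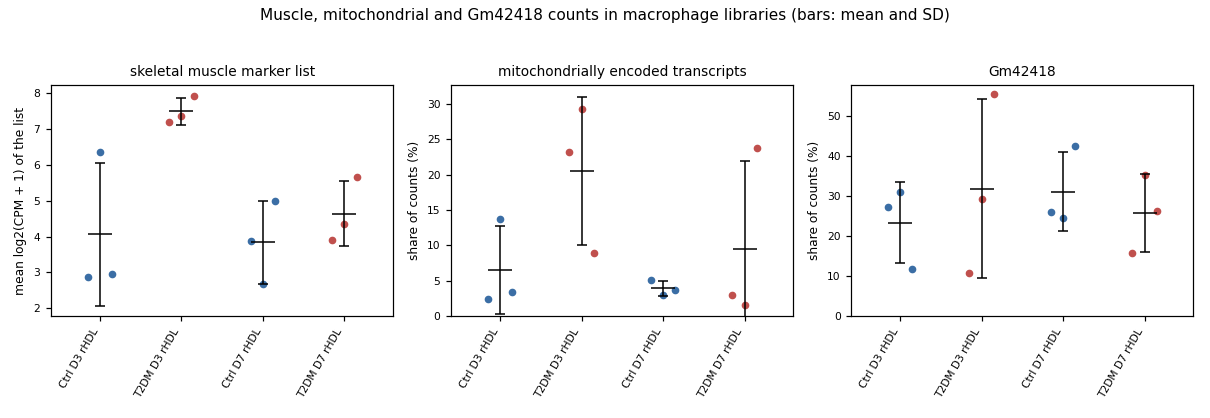
Mean of the skeletal muscle markers on a log2(CPM + 1) axis, percent of counts from mitochondrial transcripts and percent of counts from Gm42418 in the 12 macrophage libraries, with control mice in blue and T2DM mice in red, and bars for mean and SD. The 3 T2DM libraries of day 3 lie between 7.18 and 7.91 in the muscle markers, and the other 9 libraries between 2.67 and 6.36.

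Between day 3 and day 7 the MHC class II genes rose as a list in macrophages of both strains, while Fn1 and Chil3 fell. In control mice, 5 of 9 MHC class II genes rose and 7 adjusted over the list alone, with a median of 3.63 (adjusted p = 2.96e-19, adjusted p = 0.011 with an estimated correlation). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) rose by 4.00 ± 0.56, from 57.5 ± 18.8 to 922 ± 252 CPM, H2-Eb1 by 4.48 ± 0.62, H2-Aa by 3.81 ± 0.56 and Ciita, the transactivator of the class, by 4.85 ± 0.76. Of the LXR targets and efflux genes 3 rose and 4 adjusted over the list alone, with a median of 0.71 (adjusted p = 3.28e-04, adjusted p = 0.0394 with an estimated correlation): Pltp, a phospholipid transfer protein, by 3.54 ± 0.40, from 41.4 ± 9.90 to 481 ± 55.8 CPM, Abca1 by 2.43 ± 0.44 and Apoe by 2.45 ± 0.47. Tmem176b rose by 5.07 ± 0.46, from 8.89 ± 0.622 to 299 ± 162 CPM, and Tmem176a by 5.28 ± 0.81. Spic, a transcription factor of iron-recycling macrophages, rose by 6.98 ± 1.13, Gpr162 by 6.00 ± 1.00 and Cd83 by 4.88 ± 0.71.

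Spp1, the matrix protein osteopontin, fell by 4.02 ± 0.70 in control macrophages, from 4120 ± 1340 to 253 ± 145 CPM, Chil3 by 3.32 ± 0.61, Fn1, fibronectin, by 3.20 ± 0.42, Mmp8 by 2.63 ± 0.51 and the scavenger receptor Msr1 by 1.84 ± 0.33. Of the unfolded protein response genes Sdf2l1 fell by 2.21 ± 0.39, 3 fell adjusted over the list alone, and the median was -0.71 (adjusted p = 6.41e-04, adjusted p = 0.0394 with an estimated correlation). Fosb rose by 3.71 ± 0.68 among 18 immediate-early genes, 10 of which rose adjusted over the list alone. Their median was 1.63 (adjusted p = 3.05e-10, adjusted p = 0.126 with an estimated correlation). The cell cycle genes had a median of -0.97 (adjusted p = 4.21e-07, adjusted p = 0.306 with an estimated correlation), with Mcm2, a replication helicase subunit, at -2.37 ± 0.77. Il1b was at 3.56 ± 0.74 (adjusted p = 0.0631).

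In T2DM macrophages H2-Aa rose by 5.62 ± 0.61, from 31.7 ± 9.61 to 1570 ± 869 CPM, H2-Ab1 by 5.56 ± 0.60, H2-Eb1 by 5.84 ± 0.67 and Ciita by 5.58 ± 0.81, and all 9 MHC class II genes rose adjusted over the list alone, 5 of them over all genes. Their median was 4.18 (adjusted p = 4.04e-25, adjusted p = 0.0158 with an estimated correlation). Pltp rose by 2.83 ± 0.39 and the transferrin gene Trf by 4.44 ± 0.70. Chil3 fell by 3.88 ± 0.62, Fn1 by 2.98 ± 0.42 and the chemokine Ccl6 by 2.35 ± 0.42. Arg1 was at -4.08 ± 1.05 (adjusted p = 0.194) and Igf1 at 1.74 ± 0.33 (adjusted p = 0.0649) among 17 alternatively activated macrophage genes, of which Fn1 and Chil3 fell, with 3 higher and 3 lower adjusted over the list alone. The cell cycle genes had a median of -0.83 (adjusted p = 9.71e-10, adjusted p = 0.168 with an estimated correlation), with Mcm7 at -2.10 ± 0.47, Mki67 at -1.89 ± 0.57 and 10 of 32 lower adjusted over the list alone, and was -1.70 and -0.55 without day 7 library 1 and 3. The skeletal muscle markers had a median of -3.38 (adjusted p = 8.17e-16, adjusted p = 0.168 with an estimated correlation). Fibroblast markers had a median of 2.19, or 2.15 at their bounds (adjusted p = 6.64e-07, adjusted p = 0.169 with an estimated correlation).

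**Figure D5:**
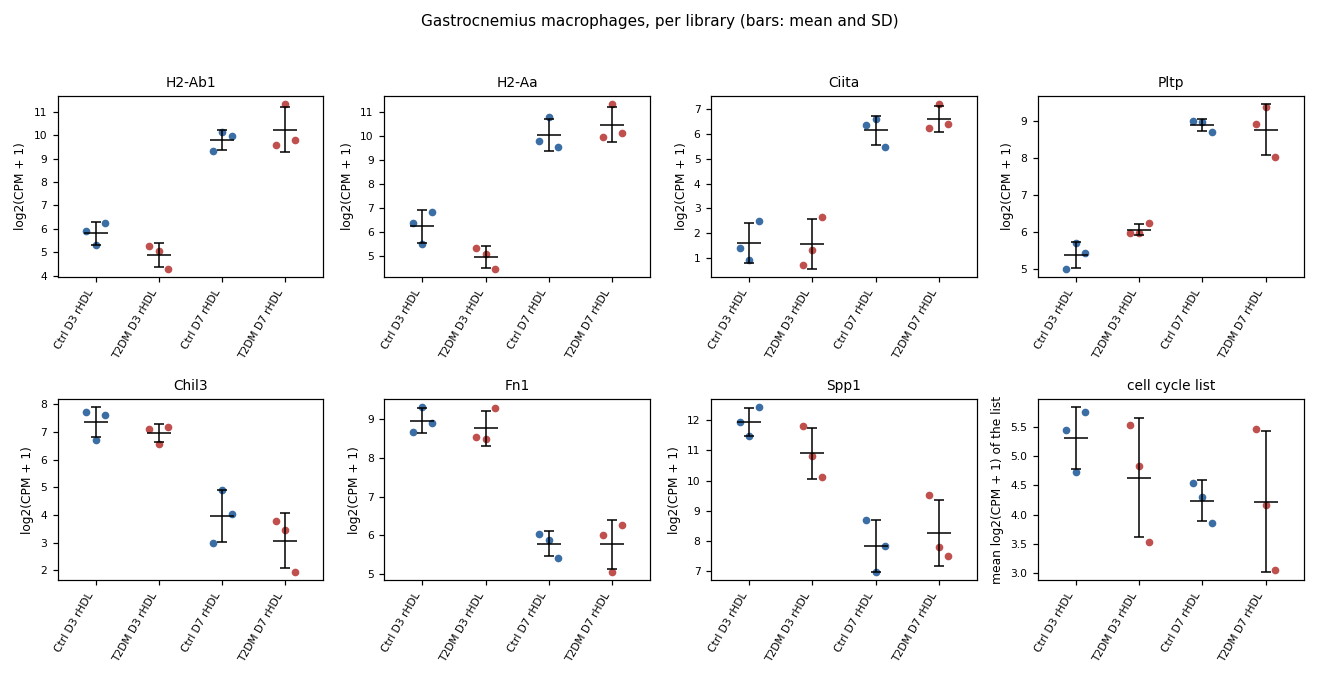
Macrophages at day 3 and day 7: each point is a library on a log2(CPM + 1) axis for H2-Ab1, H2-Aa, Ciita, Pltp, Chil3, Fn1, Spp1 and the mean of the cell cycle genes, with control mice in blue and T2DM mice in red, and bars for mean and SD. H2-Ab1 rose from 57.5 ± 18.8 to 922 ± 252 CPM in control mice and from 29.6 ± 9.92 to 1410 ± 1010 CPM in T2DM mice.

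edgeR called 46 of 11188 genes over time in control macrophages, 37 higher and 9 lower, and 20 in T2DM macrophages, 17 higher and 3 lower. Between them 17 genes were shared, all 17 in the same direction. Over all tested genes the libraries of both days did not overlap in 28.3% in control and 15.1% in T2DM mice, against 10% by chance. In control mice the count was 1, 2 and 1 without day 3 library 1, 2 and 3 and 5, 11 and 2 without day 7 library 1, 2 and 3, and in T2DM mice 4 without day 3 library 2 and 9 and 4 without day 7 library 1 and 2. The MHC class II list kept its call in all 6 fits that left out a library in each strain, and H2-Aa, H2-Ab1 and H2-Eb1 did so in T2DM mice and Tmem176b in control mice. In control mice Pltp was called in 4 of these fits and H2-Ab1 in 2. A fit of the compared groups alone gave 476 genes, all 46 among them, and 0. The change of the T2DM effect over time called 0 genes, with 249 at an unadjusted p under 0.05 and 0 by DESeq2 and voom, and Tmem176a had the smallest p at -4.01 ± 1.00 (adjusted p = 0.955). The median log2 change of all genes was 0.114 over time in T2DM macrophages and 0.131 in that interaction.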

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

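The tests of neutrophil, lymphocyte, macrophage and muscle RNA and of isolation stress and the adjustment without Ldlr were chosen after the results were seen. Groups of 4 libraries were searched for a library far from the others, which chance finds in about 1 of 20 groups.

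Of 70 list scores and 8 library values (counts, detected genes, Gm42418 and mitochondrial percent) in the 2 groups of 4 libraries, 5 list scores and 0 library values had an outlying library, all in AEC of rHDL-treated T2DM mice at day 7. The outlying score was 8.30 for the pan-endothelial markers, 6.39 for the lipid-associated macrophage genes, 2.40 for the cholesterol biosynthesis genes, 6.06 for the interferon response genes (7.54 to 7.71 in the others) and 3.01 for the lymphocyte markers. Of 46 tested values of named genes in these groups 6 had an outlying library, at 18.3 CPM for Lcn2, 93.7 for Sgk1 and 23.3 for Sh3rf1 in the same AEC group and at 286 for Adamts4, 67.2 for Ifit2 and 77.7 for Zbp1 in EC of T2DM mice at day 3.

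The lists were also tested on the interactions, where 22 were called with the preset correlation and none with an estimated one. The change with rHDL in AEC at day 3 was lower in T2DM than in control mice for the pan-macrophage markers (adjusted p = 4.809e-07), the interferon response genes (4.809e-07), the pro-inflammatory macrophage genes (5.641e-05), the MHC class II genes (0.0005112) and the NF-kB targets (0.01204), each with adjusted p = 0.1508 to 0.7709 with an estimated correlation. At day 7 the same test called the pan-macrophage markers (0.000593), the glycolysis genes (0.008686) and the lipid-associated macrophage genes (0.02542), all lower, and for the mitochondrially encoded transcripts (0.008686), which were higher, each with adjusted p = 0.7814 with an estimated correlation. For the T2DM effect by day in EC it called the interferon response genes (0.0003573, lower at day 7) and the smooth muscle markers (0.04512, higher), each with adjusted p = 0.8998 with an estimated correlation. In macrophages it called the skeletal muscle markers (7.783e-13), the mitochondrially encoded transcripts (0.000171), the immediate-early genes (0.000128), the smooth muscle markers (0.001072), the pan-endothelial markers (0.001447), the tip cell genes (0.01538) and the basement membrane genes (0.0222), all lower at day 7, each with adjusted p = 0.6132 to 0.6151 with an estimated correlation. The fibroblast markers (0.0002587), the interferon response genes (0.004185), the cholesterol biosynthesis genes (0.009503) and the MHC class II genes (0.009948) were higher at day 7, each with adjusted p = 0.6132 to 0.6151 with an estimated correlation.

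The genes that rose in T2DM AEC after PBS at day 7 came with neutrophil markers in libraries 1 and 3 of that group. The 158 genes (median log2 change 1.85) were selected as higher, so the 75th percentile of 1.22 of the immediate-early genes decides nothing on isolation stress. With the neutrophil score as a covariate the median ratio of a gene's change to its change without it was 0.41 (quartiles 0.2 and 0.64), with a median change of 0.69 in place of 1.85 at an SE of 0.44 in place of 0.43, and 1 of the genes was still called. Neutrophil RNA and a response of AEC in the same mice cannot be told apart, since the score is high in 2 libraries of a single group, and the biological difference of the strains stays open as untested.

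The interferon response genes stood higher in T2DM mice at day 3 in EC (median 1.75) and AEC (median 2.39). Macrophage RNA is argued against in both. In CPM the list gained a median of 2.86 (EC) and 5.63 (AEC) times its level in T2DM macrophages of day 3. The macrophage markers held 0.0207 and 0.00484 times theirs and changed by -0.85 and -0.18 (log2) in summed CPM. As a covariate they left a median of 1.38 in EC. Lymphocyte RNA is argued against in EC. There its markers (103 and 101 counts in T2DM and control mice) changed by -0.57 in summed CPM. The upper 95% bound of 1.11 is under the list's lower quartile of 1.45. In AEC these markers had 45 and 56 counts, too few to bound their change of 0.18 (upper bound 2.47), so lymphocyte RNA stays open there. Covariate medians of 2.48 (macrophages, AEC), 1.73 (lymphocytes, EC) and 2.39 (lymphocytes, AEC) decide nothing, as these scores differed by less than their SD. A difference of the strains or of their tissue stays open as untested.

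Skeletal muscle and mitochondrial transcripts stood high in T2DM macrophages at day 3. Over the 12 macrophage libraries the muscle score rose with the mitochondrial percentage (Spearman rho 0.76, permutation p 0.0065, Pearson r 0.74, permutation p 0.0068, and r 0.82 without the 2 libraries farthest from the median), which is consistent with carried-over muscle RNA. A single library was not the cause, since the list median was 2.50 to 6.43 when 1 library was left out. Why T2DM samples held more of it was not tested.

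Each comparison was repeated on other splits of its libraries. For T2DM in EC at day 3, the real count of 2 genes was reached in 1 of 35 splits, the real one, and the highest other was 0. Ldlr, which the T2DM strain lacks, is 1 of these 2 genes, and with Ldlr left out of the adjustment the real count was 0, so the splits decide nothing on chance. For rHDL in T2DM AEC at day 7, 2 of 35 splits gave as many genes as the real 122, and chance cannot be excluded. The highest other, 353, grouped T2DM PBS library 2 with rHDL libraries 2, 3 and 4, which points to a structure of the samples. A real count of 0 is reached by every split, so the splits decide nothing for T2DM in AEC after rHDL at day 7 (real 0, highest other 0) and for time in T2DM EC (0 and 1). Nor do they for the interactions over 24 splits each in AEC at day 3 (0 and 0), AEC at day 7 (0 and 124, which points to a structure of the samples), EC (0 and 0) and macrophages (0 and 0).

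The other comparisons have 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 0 for rHDL in control AEC at day 3, in control AEC at day 7 and in T2DM AEC at day 3. They were 2 and 0 for T2DM in AEC after PBS at day 3, 235 and 243 at day 7 and 1 and 0 after rHDL at day 3. Over time they were 160 and 0 in control AEC, 235 and 26 in T2DM AEC, 0 and 0 in control EC, 46 and 0 in control macrophages and 20 and 0 in T2DM macrophages. For T2DM they were 2 and 8 in EC at day 7, where the split with 8 grouped control libraries 2 and 3 with T2DM library 2 and points to a structure of the samples, and 0 and 0 in macrophages at day 3 and 0 and 1 at day 7. The split with 243 grouped control PBS library 3 with T2DM PBS libraries 1 and 3.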

How the results depend on the processing

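The covariates, the removed genes, the adjustment without Ldlr, the libraries left out for their share of Gm42418 and the averaged comparisons were chosen after the data were seen. The other alternatives were fixed beforehand.

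DESeq2 called 1, 1, 1 and 361 genes for rHDL in AEC (control day 3, control day 7, T2DM day 3, T2DM day 7; edgeR 0, 0, 0 and 122, of which DESeq2 called 121). It called 40, 548, 10 and 6 for T2DM in AEC (PBS day 3, PBS day 7, rHDL day 3, rHDL day 7; edgeR 2, 235, 1 and 0, of which DESeq2 called all 235 at PBS day 7), 17 for the AEC interaction at day 7 (0), 255 and 468 over time in control and T2DM AEC (160 and 235), 64 and 631 for T2DM in EC at day 3 and day 7 (2 and 2), 81 and 26 over time in control and T2DM EC (0 and 0), 81 and 1 for T2DM in macrophages (0 and 0) and 288 and 381 over time in them (46 and 20).

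In that order, voom called 401 for rHDL in T2DM AEC at day 7, 121, 661, 3 and 1 for T2DM in AEC, 1 for the interaction at day 7, 818 over time in T2DM AEC, 22 in EC at day 3, 2 and 30 over time in EC, 366 in macrophages at day 3 and 1989 and 111 over time in macrophages. Without a filter on low counts edgeR called 80, 62, 56 and 408 for rHDL, 214, 669, 107 and 42 for T2DM in AEC, 86 and 187 for the interactions, 337 and 520 over time in AEC, 18 and 300 in EC, 22 and 13 over time in EC, 1 and 1 in macrophages and 35 over time in T2DM macrophages. The cause of these differences was not tested.

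Fits of the compared groups alone have fewer libraries for the spread and called 6 and 0 for rHDL in T2DM AEC at day 3 and day 7, 86 and 1 for T2DM after PBS, 79 and 36 over time in AEC, 5 and 0 in EC, 1 in macrophages at day 7 and 476 and 0 over time in macrophages. With a replicate block edgeR called 8 for rHDL in T2DM AEC at day 7, 0 for T2DM after rHDL in AEC at day 3, 0 in EC at day 7 and 11 over time in T2DM macrophages. A non-robust fit called 0 for T2DM after rHDL in AEC at day 3 and 0 in EC at day 7, and a stricter filter called 0 in EC at day 7. The neutrophil covariate left 1 for rHDL in T2DM AEC at day 7, 1 for T2DM after PBS at day 7 and 93 over time in T2DM AEC. Without libraries over 40% Gm42418 there were 1 in EC at day 7, 2 and 7 over time in EC and 104 and 7 over time in macrophages, and the muscle covariate left 5 over time in T2DM macrophages. With Ldlr left out of the adjustment edgeR called 0 in EC at day 3 and 0 at day 7, and every other count stayed within 1.5 times. RLE size factors and removal of the ribosomal RNA locus and mitochondrial genes kept every count within 1.5 times, and RLE moved the median of all genes by at most 0.07.

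Of 191 list calls 10 held with an estimated correlation. With the muscle covariate the interferon response genes in T2DM macrophages at day 3 had a median of 0.66 in place of -0.70. Without T2DM macrophage library 3 of day 7 the pan-endothelial markers had a median of -0.23 in place of 0.90 and the mitochondrially encoded transcripts one of -0.89 in place of 1.45 (1.88 and 1.83 without libraries 1 and 2). The other list calls kept direction and side of the threshold in 1067 of 1320 fits that left out a library, in 51 of 80 with the neutrophil covariate, 24 of 66 with the muscle covariate, 17 of 19 with the macrophage covariate, all 19 with the lymphocyte covariate and all 185 without the ribosomal RNA locus and mitochondrial genes. Values of named genes kept both in all 235 with RLE size factors, 227 of 229 with Ldlr left out of the adjustment, 228 of 235 with a non-robust fit, 228 of 231 with a stricter filter, 196 of 235 with a replicate block (36 no longer past the threshold, 3 newly past), 184 of 235 with voom (12 and 39), 183 of 231 with DESeq2 (0 and 48), 187 of 235 without a filter (1 and 47), 109 of 197 in fits of the compared groups (79 and 9), 75 of 145 with the neutrophil covariate (70 and 0) and 1526 of 2000 when a library was left out (432 and 42), and 0 changed direction.

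Leaving out 1 library at a time gave 0 genes throughout for rHDL in control AEC at both days and in T2DM AEC at day 3, and 0 to 727 in T2DM AEC at day 7. For T2DM in AEC it gave 2 to 5 and 2 to 1054 after PBS and 0 to 1 and 0 to 1 after rHDL, for the interactions 0 throughout at day 3 and 0 to 184 at day 7, and over time 96 to 220 in control and 105 to 719 in T2DM AEC. In EC it gave 1 to 6 and 0 to 347 for T2DM at day 3 and day 7, 0 to 3 and 0 over time and 0 for the interaction. In macrophages it gave 0 to 1 and 0 for T2DM, 1 to 11 and 4 to 17 over time and 0 for the interaction. The number of list calls was 176 to 220. The reversal of the T2DM effect moved between -0.006 and 0.076 at day 3 and between -0.612 and -0.144 at day 7. The libraries that moved a count by over 1.5 times are named beside each comparison of the report. The number of counts limits genes at low CPM, and the spread between libraries limits the calls in macrophages, where simulated genes changed 4-fold gave 0 calls.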

Other observations

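The averaged comparisons, their genes and the tests on them were chosen after the results of single arms were seen.

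Averaged over the 4 arms of AEC, the LXR targets and efflux genes stood higher and the arterial and flow-responsive genes lower in T2DM mice, each as a list. Gramd1b rose by 2.13 ± 0.16 on the log2 scale (adjusted p = 1.94e-09), Abcg1 by 1.59 ± 0.19 (adjusted p = 2.27e-05), Abca1 by 1.61 ± 0.28 and Mylip by 1.34 ± 0.19, and 6 of 16 LXR targets and efflux genes rose and 1 fell (median 0.45, adjusted p = 2.60e-10, adjusted p = 0.00165 with an estimated correlation). Ldlr fell by 3.60 ± 0.61. The insulin-degrading enzyme Ide fell by 1.02 ± 0.14, Pdgfd, a growth factor for mural cells, by 1.26 ± 0.18, and Robo2, a guidance receptor, by 4.31 ± 0.58. The pan-endothelial markers had a median of -0.15 (adjusted p = 0.0107, adjusted p = 0.124 with an estimated correlation), and the call was lost with the neutrophil covariate (-0.15, adjusted p = 0.066). Capillary and venous markers had a median of -0.19 (adjusted p = 0.0657), and were called with that covariate (-0.18, adjusted p = 0.00313). The arterial markers had a median of -0.33 (adjusted p = 5.37e-05, adjusted p = 0.0456 with an estimated correlation), with Cxcl12 down by 0.59 ± 0.11, and the flow-responsive genes one of -0.32 (adjusted p = 1.61e-04, adjusted p = 0.0456 with an estimated correlation), with thrombomodulin (Thbd) down by 0.85 ± 0.15. The water channel Aqp1 fell by 0.63 ± 0.12 and Apoe by 0.53 ± 0.11. Angptl4 rose by 2.01 ± 0.34, the desaturase Scd1 by 1.61 ± 0.33, Fasn, the fatty acid synthase, by 1.27 ± 0.28 and the lipase Pnpla2 by 0.64 ± 0.13. The cholesterol biosynthesis genes had a median of -0.24 (adjusted p = 0.00392, adjusted p = 0.121 with an estimated correlation), and of -0.15 with the neutrophil covariate, where the call was lost. The NF-kB targets had a median of 0.41 (adjusted p = 8.94e-04, adjusted p = 0.026 with an estimated correlation), and of 0.19 with the neutrophil covariate. The pro-inflammatory macrophage genes had a median of 1.67 (adjusted p = 0.00154, adjusted p = 0.121 with an estimated correlation), and of 0.55 with that covariate (adjusted p = 0.108), and the neutrophil markers had one of 3.29 (adjusted p = 0.103). Without T2DM day 7 PBS library 1 the NF-kB median was 0.27, and without control day 7 PBS library 1 the arterial median was -0.21. The interferon response genes had a median of 1.25 (adjusted p = 7.41e-19, adjusted p = 0.124 with an estimated correlation) and the MHC class II genes one of 2.89 (adjusted p = 4.38e-11, adjusted p = 0.0781 with an estimated correlation).

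edgeR called 137 genes, 74 higher and 63 lower, with 1753 at an unadjusted p under 0.05, DESeq2 449, voom 1110, no filter 606, a stricter filter 167, a replicate block 147 and the neutrophil covariate 66, of which 47 were among the 137. Leaving out 1 library moved the count to 82 without control day 3 PBS library 2, 68 and 80 without control day 3 rHDL library 1 and 3, 76 and 78 without control day 7 PBS library 1 and 3, and 60, 221 and 91 without control day 7 rHDL library 1, 2 and 3. It was 75 and 74 without T2DM day 3 PBS library 1 and 3, 81 without T2DM day 3 rHDL library 1, 284, 401 and 81 without T2DM day 7 PBS library 1, 2 and 3, and 80 without T2DM day 7 rHDL library 3. The called genes and lists named here were called in all 25 of these fits. No other of 40 splits that kept the arms gave as many genes (highest 3). The comparison was chosen after its arms were seen, so these splits do not exclude chance. With Ldlr left out of the adjustment the real count was 135 and the highest other 3.

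Averaged over both days, the cholesterol biosynthesis genes stood lower as a list in EC of T2DM mice. Ldlr fell by 5.20 ± 0.46, Dhcr24, the last enzyme of cholesterol biosynthesis, by 3.53 ± 0.57, and the list had a median of -0.53 (adjusted p = 1.92e-05, adjusted p = 0.0198 with an estimated correlation). Abcg1 rose by 2.02 ± 0.30, Mylip by 1.54 ± 0.25 and Abca1 by 1.18 ± 0.24. Of 23 interferon response genes 13 rose, with a median of 1.52 (adjusted p = 9.97e-28, adjusted p = 0.0926 with an estimated correlation), Gbp9 by 1.80 ± 0.22, Irgm2 by 2.46 ± 0.35, the nucleic acid sensor Zbp1 by 3.20 ± 0.50 and Stat1 by 1.77 ± 0.34. Ide fell by 1.17 ± 0.23 and Col3a1 by 1.40 ± 0.24. The pan-macrophage markers had a median of -1.27 (adjusted p = 1.20e-09, adjusted p = 0.307 with an estimated correlation), and of -0.80 without control day 7 library 1. Fibroblast markers had a median of -0.67 (adjusted p = 1.88e-05, adjusted p = 0.0926 with an estimated correlation), LXR targets and efflux genes one of 0.58 (adjusted p = 1.06e-05, adjusted p = 0.0926 with an estimated correlation) and cell cycle genes one of -0.46 (adjusted p = 2.48e-04, adjusted p = 0.592 with an estimated correlation).

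edgeR called 119 genes in EC, 82 higher and 37 lower, with 2070 at an unadjusted p under 0.05, DESeq2 706, voom 588, RLE size factors 98, no filter 383, a replicate block 47 and 106 without libraries over 40% Gm42418. Without a library the count was 12, 17 and 40 (control day 3 library 1, 2 and 3), 305 and 406 (control day 7 library 2 and 3), 52, 35 and 66 (T2DM day 3 library 1, 2 and 3) and 32, 289 and 20 (T2DM day 7 library 1, 2 and 3). Ldlr, Gbp9, Irgm2, Abcg1, Mylip and Zbp1 were called in all 13 of these fits, Dhcr24 and Col3a1 in 12, Stat1 and Ide in 7 and Abca1 in 6, and the 6 lists in all 13. No other of 40 splits gave a gene (highest 0), but the single days were seen first, so chance is not excluded. With Ldlr left out of the adjustment the real count was 101 and the highest other 0.

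Averaged over the 4 arms of AEC, rHDL called 0 genes by edgeR, with 855 at an unadjusted p under 0.05, DESeq2 38 and voom 42. The smallest adjusted p was 0.247, of Zhx3 at -0.59 ± 0.12, followed by Endov at 2.10 ± 0.44, Pafah1b2 at -0.60 ± 0.13, Mat2a at -0.60 ± 0.13, Rhob at -0.70 ± 0.16 and Dusp1 at -1.07 ± 0.23. The immediate-early genes had a median of -0.52 (adjusted p = 1.34e-08, adjusted p = 0.384 with an estimated correlation), and of -0.34 without control day 7 PBS library 3 and -0.31 with the neutrophil covariate. The interferon response genes had a median of 0.48 (adjusted p = 7.67e-07, adjusted p = 0.662 with an estimated correlation), of 0.27 without control day 3 rHDL library 2 and of 0.28 with the neutrophil covariate, where the call was lost. MHC class II genes had a median of 1.24 (adjusted p = 7.68e-04, adjusted p = 0.662 with an estimated correlation), and of 1.08 without control day 7 rHDL library 2, where the call was lost. Glycolysis genes had a median of -0.22 (adjusted p = 0.0112, adjusted p = 0.662 with an estimated correlation), with the call lost without control day 3 PBS library 1 (-0.12), T2DM day 7 PBS library 1 (-0.10) or with the neutrophil covariate (-0.11). The hypoxia response genes had a median of -0.22 (adjusted p = 0.0112, adjusted p = 0.662 with an estimated correlation), with -0.37 without T2DM day 7 rHDL library 1 and the call lost without control day 7 PBS library 1 (-0.19), control day 7 rHDL library 2 (-0.18), T2DM day 7 PBS library 1 (-0.09) or with the neutrophil covariate (0.07). The flow-responsive genes had a median of -0.09 (adjusted p = 0.0257, adjusted p = 0.481 with an estimated correlation), and -0.15 without T2DM day 7 rHDL library 1. Their call was lost with that covariate (-0.01) and without control day 3 rHDL library 3 (-0.06), control day 7 PBS library 3 (-0.09) or rHDL library 2 (-0.12), T2DM day 3 PBS library 2 (-0.07) or T2DM day 7 PBS library 1 (-0.02). Without T2DM PBS library 2 of day 7 the count was 86. A real count of 0 is reached by all 40 splits (highest other 1), so the splits decide nothing on chance.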
